A study of Mus musculus with 36 samples.

How the data were processed

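The material was total RNA from the forebrain and the cerebellum of mice, hybridised to 1-colour Affymetrix arrays with 45101 probe sets, per the labels and the probe table. The 36 arrays fell into 12 groups of 3. They covered 3 lines, which the labels call stg, tg and lh, each with a -/- and a +/+ group in both tissues. The symbols were read as stargazer, tottering and lethargic, since that is how these symbols are used for mouse mutants with changes in Cacng2, Cacna1a and Cacnb4. The labels do not spell the names out.

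The deposited values were linear signal intensities, 1 per probe set and array. How the authors made them from the scans is not given in the sources used here. The deposited intensities themselves show a common scaling: the mean after trimming 2% of the probe sets at each end was 150 on every array. The values ran from 0.0223 to 16805, with no negative values. No detection calls were used, so the limit of detection of a probe set is unknown here. For arrays, the number per group limits the precision.

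From these values log2 of the signal plus a constant was computed. The constant was 2.98, the 10th percentile of all values, which shrinks log2 changes of probe sets near the floor. Array medians of the log2 values ran from 5.40 to 5.72, a span of 0.326 and below the limit of 0.5 that would have called for quantile normalization, so none was applied. The 64 AFFX control probe sets were left out. Probe sets with a mean above the 40th percentile over the arrays of a fit were kept, which left 27022 in each fit.

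Gene symbols came from the probe table. Of the probe sets, 34958 had 1 symbol, 932 had several and 9211 had none. By Entrez ID, 34754 of those with 1 symbol matched the reference annotation of the mouse assembly GRCm38.p6 and 204 did not. Only probe sets with 1 symbol were named. The annotation gave the neighbours of each mutated gene, counted in windows.

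Groups were compared with limma 3.58.1 in R 4.3.3, with a mean per group, an intensity trend in the empirical Bayes step and two-sided moderated tests. Each -/- group was compared with the +/+ group of its line in a fit over the 18 arrays of a tissue. The same fits gave the mean effect of the 3 lines, the moderated F test of whether the effect differed among lines, and the F test among the 3 +/+ groups. A fit over all 36 arrays gave the difference of the effect between tissues and the difference between tissues in +/+ mice. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. They measure the spread between these samples, since the labels do not say clearly that each array is a separate animal, nor whether both tissues came from the same animals.

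Lists of genes were tested with limma's camera at a preset correlation of 0.01, each gene represented by the probe set with the highest mean, with at least 4 measured members. Camera with an estimated correlation and limma's fry were run beside it. Of the 26 lists, 25 were for testing. They held ion channels, receptors, calcium handling, activity-regulated genes, neuropeptides, release machinery, cell type markers, markers of neighbouring brain regions, stress and interferon genes, red blood cell genes, and a literature list of genes described in the cerebellum of calcium channel mutants. The list of sex-linked genes was read array by array and not tested. The red blood cell list had too few measured members in either tissue, and the list of brainstem and spinal cord markers too few in cerebellum.

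The tests, the filter, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the mutated genes and, among called probe sets with no overlap between the 3 -/- and the 3 +/+ arrays, the 12 largest rises and 12 largest falls. It added the called members of each list, at most the 4 largest changes, and the literature list in the cerebellum. Where fewer than 5 genes passed, the 5 with the smallest p were named. For the mean effect and the tests of differences the 8 with the smallest p were named, and for overlaps between lines the first 10. Chance puts 10% of probe sets without overlap when 3 arrays are set against 3.

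Genes within 10 Mb of the mutated gene were compared with all others by a two-sided Fisher's exact test. Signs of RNA quality were compared with two-sided exact permutation tests. Whether replicate numbers pair the cerebellum arrays was checked from the correlation of same-numbered arrays' deviations from their group means, with 0.1 in every pair as the limit. In stg the 3 pairs reached 0.156, 0.188 and 0.380, each highest with its own number, so the stg numbers were read as pairs from the data, although in stg they also go with sex and the series of records. The labels give no pairing, the fit without the block was kept as set, and in tg and lh 1 pair each lay under the limit. Alternatives were no filter, a filter at the 60th percentile, quantile normalization, a constant of 1, no intensity trend, array weights, a fit on the 6 arrays compared, the replicate number as a block in cerebellum, each array left out in turn, and windows of 5 and 20 Mb and the whole chromosome. A block for the 2 series of consecutive records and a fit without the 3 arrays with pituitary transcripts were chosen after seeing the data.

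The fits were tested on simulated data with 200 of 27022 probe sets changed. A change of 1 on the log2 scale was recovered for 62.7% of the changed probe sets in stg cerebellum, 62.7% in tg cerebellum, 74.6% in lh cerebellum, 61.2% in stg forebrain, 70.1% in tg forebrain and 53.7% in lh forebrain. At a change of 0.5 the shares were 13.4%, 16.4%, 11.9%, 14.9%, 14.9% and 10.4% in the same order, so most changes of that size would be missed. These shares hold for 200 changed probe sets and independent normal noise. Where fewer probe sets change, the adjusted threshold is stricter and the shares would be lower. Figures were drawn with matplotlib 3.10.9.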

Results

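RNA was measured in the forebrain and the cerebellum of 3 lines of mutant mice, on 36 arrays in 12 groups of 3. The lines are neurological mutants of voltage-gated calcium channel genes that share ataxia and absence seizures. The stg line is read here as stargazer, with a change in Cacng2, which encodes a channel gamma subunit that also carries AMPA receptors to the synapse. The tg line is read as tottering, with a missense change in Cacna1a, the pore of the P/Q-type channel, and lh as lethargic, with a change in Cacnb4, an auxiliary beta subunit. Each line has -/- and +/+ arrays in both tissues, so the design asks which transcripts differ with each mutation, in which tissue, and which differ in more than 1 line.

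The 3' to 5' difference of the Gapdh and Actb control probe sets was taken as a sign of RNA quality. For Actb it did not overlap between -/- and +/+ in stg forebrain, where -/- minus +/+ was -0.19, and in lh forebrain, where it was -0.04 (exact permutation p = 0.1 in each, the smallest that 3 arrays against 3 allow). The other exact p-values were 0.6 to 1. The mean correlation of an array with the others of its tissue was taken across probe sets. In forebrain it was lowest for lh-/- replicate 3 (0.937) and tg+/+ replicate 2 (0.938), and 0.943 or higher for the other arrays. In cerebellum it was lowest for 3 -/- arrays, stg-/- replicate 3 (0.940), lh-/- replicate 1 (0.941) and stg-/- replicate 2 (0.942). Xist and the Y-linked Eif2s3y read 2 females and 1 male in each stg group, 1 female and 2 males in each lh group and 3 males in each tg group, so sex was balanced between -/- and +/+. The records form 2 series, of 20 and 16 arrays, each holding both genotypes of every line and tissue. In stg and lh these series split the arrays as sex does. A block for line and series, chosen after seeing the data, gave 689, 287 and 137 calls in stg, tg and lh cerebellum against 352, 155 and 42 without it, and 3, 77 and 2 in forebrain against 3, 51 and 4. Of these forebrain calls 2, 49 and 2 were made both with and without the block.

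Between tissues of +/+ mice, Enc1, an actin-binding protein of neurons, was lower in cerebellum by -5.25 on the log2 scale (SE 0.06). Chn2, a Rac GTPase activator of granule cells, was higher in cerebellum by 3.51 (SE 0.06). Basp1 (-4.80), Rgs4 (-4.43), Rasgrf2 (-4.32), Hpcal4 (-4.25) and Cx3cl1 (-3.40) were also lower in cerebellum and Inpp5a (2.68) higher, and of 27022 probe sets 15726 passed adjusted p 0.05, 8749 higher in cerebellum and 6977 lower.

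The mutated genes were read first. In stg-/- mice the main probe set of Cacng2 had a signal of 4.31 ± 2.67 (SD, n = 3) in forebrain against 265 ± 35.7 in stg+/+, a change of -5.26 (SE 0.22, adjusted p = 8.49e-11). In cerebellum it was 3.91 ± 1.28 against 636 ± 188, a change of -6.51 (SE 0.21, adjusted p = 8.00e-13). Both stg-/- signals lie near the added constant of 2.98, so the size of these changes depends on it, and a smaller constant gives larger ones. Another Cacng2 probe set changed by -3.61 in forebrain and by -4.53 in cerebellum. The last Cacng2 probe set, near the floor, was at -1.24 in cerebellum without passing (adjusted p = 0.334) and below the filter in forebrain. In lh-/- mice Cacnb4 was 131 ± 24.4 against 311 ± 10.6 in forebrain, a change of -1.24 (SE 0.13, adjusted p = 0.000382), and its other probe sets changed by -1.27 and -1.08, the latter (adjusted p = 0.0285) lost when any 1 of the 6 arrays was left out. In lh cerebellum the same Cacnb4 probe set was 404 ± 29.5 against 733 ± 112, a change of -0.84 (SE 0.13, adjusted p = 0.00763), and the other probe sets did not pass. For Cacna1a the 3 measured probe sets were at -0.57, 0.18 and 0.32 in tg forebrain and at -0.28, 0.13 and 0.24 in tg cerebellum, none passing; a missense change need not alter the level of the transcript. None of the 3 genes passed in the other lines. In stg cerebellum the Cacnb4 probe sets were at -0.26 to -0.51, with adjusted p from 0.111 to 0.481.

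**Figure D1:**
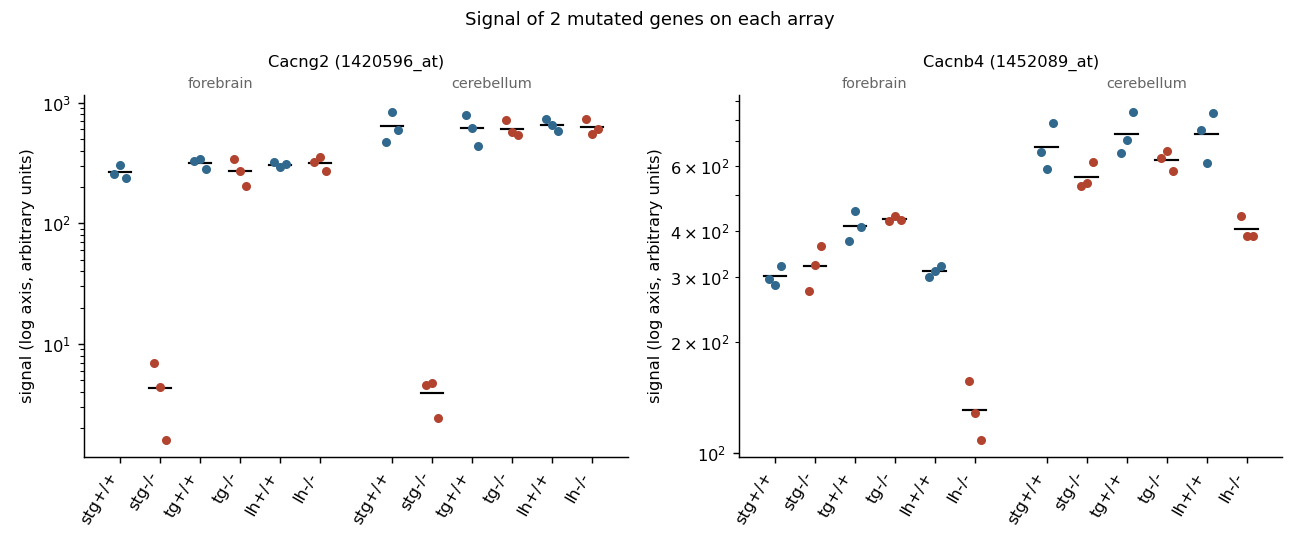
Signal of a Cacng2 and a Cacnb4 probe set on each array, on a log axis, by line, genotype and tissue, with points for arrays and bars for the mean of 3. Cacng2 lies near 4.31 and 3.91 in the stg-/- groups and Cacnb4 is lower in lh-/- than in lh+/+ mice of the same tissue.

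Loss of Cacng2 went with the longest list of changes, in the cerebellum. Mapk13, a stress-activated p38 kinase, rose from 10.04 ± 4.58 to 320.3 ± 131 (SD, n = 3), a change of 4.61 (SE 0.41, adjusted p = 4.15e-06). Nos1, the neuronal nitric oxide synthase, rose from 459.7 ± 12.9 to 1397 ± 94.98, a change of 1.60 (SE 0.12, adjusted p = 5.86e-07). Bdnf, a neurotrophin of granule cells, fell from 105 ± 40.9 to 19.0 ± 13.0, a change of -2.44 (SE 0.35, adjusted p = 0.000713), and another Bdnf probe set changed by -1.48. Ncald, a neuronal calcium sensor, fell from 727 ± 82.3 to 244 ± 33.8, a change of -1.57 (SE 0.12, adjusted p = 5.86e-07). Further rises were those of Mtm1 (2.41), a phosphoinositide phosphatase, Homer2 (2.07), a postsynaptic scaffold, Scn3b (1.81), a sodium channel beta subunit, the nociceptin receptor gene Oprl1, and the formin gene Inf2 (1.72), followed by Mndal (1.61), Igsf3 (1.53), Tcerg1l (1.48), Nectin3 (1.38) and Gprin3 (1.37). Besides Cacng2, the largest falls were those of Aqp6 (-2.51), an aquaporin, Prr16, Pde1c (-1.87), a calmodulin-dependent phosphodiesterase, Pappa (-1.87), Cbx7 (-1.73), a Polycomb protein, Ltbp2 (-1.72), Tbata (-1.68), Gcnt1 and the ryanodine receptor Ryr3 (-1.47).

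For probe sets changed, stg -/- versus +/+, cerebellum, the count was 352, 142 higher and 210 lower, in 243 named genes. Leaving out stg+/+ replicate 1, stg+/+ replicate 3 or stg-/- replicate 3 gave 225, 231 or 233, and a fit on the 6 arrays alone gave 194. Same-numbered stg arrays deviated together, and with the replicate number as a block in the fit of the 3 lines the count was 1018. Of the 47 named called probe sets, 27 passed under all alternatives and with each array left out.

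By list, 17 calcium channel subunits were measured in stg cerebellum. Cacna1d (0.79) and Cacna2d3 (0.48), subunits of L-type and other channels, rose, Cacng2 fell and 14 did not pass; adjusted over the list alone 5 rose and 3 fell. The mean of that list was -0.27 and its median 0.09. Of 22 sodium, potassium and HCN channels Scn3b rose and Kcnj3 (-0.82), Scn2a (-0.70) and Kcnd2 (-0.58) fell; adjusted over the list alone 3 rose and 4 fell. Among 19 genes of calcium buffering, release and extrusion Ryr3, the kinase Camk4 (-0.76) and the sodium-calcium exchanger Slc8a1 (-0.50) fell, and adjusted over the list alone 3 rose and 5 fell. Grik3 (-0.66) was the called member of 14 glutamate receptors, and adjusted over the list alone 1 fell. Gabra6 (-0.41; 5296 ± 92.2 against 7052 ± 271), a receptor subunit of granule cells, was the called member of 13 GABA genes, and adjusted over the list alone 2 fell. Of 22 release genes Slc17a6 (0.88), a vesicular glutamate transporter, rose and Rims1 (-0.60) fell; adjusted over the list alone 2 rose and 6 fell. None of these 6 lists was shifted as a set, with adjusted p of 0.688, 0.0538, 0.391, 0.972, 0.661 and 0.0616.

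The 4 lists shifted as a set in stg cerebellum were each lost with an estimated correlation. Purkinje cell markers were shifted upward, with 15 of 17 above 0 (mean 0.26, adjusted p = 8.40e-06; adjusted p = 0.279 with an estimated correlation). No Purkinje marker passed over all genes, and 7 rose adjusted over the list alone. Microglia markers were shifted upward, 12 of 12 above 0, with none passing over all genes and 1 rising adjusted over the list alone (adjusted p = 0.0228; adjusted p = 0.279 with an estimated correlation). Leaving out stg-/- replicate 2, stg-/- replicate 3 or stg+/+ replicate 1 took the adjusted p of the list microglia markers, stg cerebellum, to 0.0951, 0.0807 or 0.0638, and no filter took it to 0.156, within a range of 0.00413 to 0.279 over all alternatives and left-out arrays. Neuropeptides and secreted factors were shifted downward, with Bdnf and the granins Chgb (-0.82) and Scg2 (-0.60) falling, 9 of 12 not passing and 5 falling adjusted over the list alone (adjusted p = 0.00116; adjusted p = 0.166 with an estimated correlation). Activity-regulated genes were shifted downward, with Jun (-0.65) and Dusp5 (-0.78) falling, Gadd45g (0.67) rising, 21 of 24 not passing, and 1 rising and 3 falling adjusted over the list alone (adjusted p = 0.00717; adjusted p = 0.428 with an estimated correlation). Among other lists Gfap (0.93), the astrocyte filament, rose, and of the thalamus list Ntng1 (-1.15) fell and Slc17a6 rose.

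On the literature list, Bdnf, Ryr3 and Gabra6 fell in stg cerebellum and 12 of 15 did not pass; adjusted over the list alone 2 rose and 4 fell (list adjusted p = 0.688, mean -0.10, median 0.08). Th (0.23), Calb1 (0.33), Pvalb (0.33), Npy (0.29), Ryr1 (0.32), Cacna1c (0.42), Gabrd (-0.33), Gabrb2 (-0.17), Calb2 (0.24), Gria2 (0.08), Gria4 (0.08) and Ntrk2 (0.04) were those not passing. With the replicate number as a block Calb1, Pvalb and Gabrd passed as well.

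The stg forebrain had far fewer changes. Besides both probe sets of Cacng2, Arhgap39 fell from 457 ± 60.9 to 188 ± 36.7 (SD, n = 3), a change of -1.28 (SE 0.20, adjusted p = 0.0488). Mtm1 (1.80, adjusted p = 0.0781), P3h2 (1.66, adjusted p = 0.273) and the splicing factor Rbfox2 (0.75, adjusted p = 0.798) did not pass. Of 27022 probe sets 3 passed in limma, none higher, and 690 had an unadjusted p under 0.05. The call of Arhgap39, unlike those of Cacng2, was lost when any 1 of the 6 arrays was left out.

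In stg forebrain 8 of 24 lists were shifted. In the same comparison the 3' to 5' difference of Actb was lower in -/- by -0.19, without overlap (exact permutation p = 0.1, the smallest that 3 arrays against 3 allow). Neuropeptides and secreted factors were shifted upward, with 18 of 20 above 0, a mean of 0.19, no member passing over all genes and 2 rising adjusted over the list alone (adjusted p = 2.57e-06; adjusted p = 0.0122 with an estimated correlation). Olfactory bulb markers (adjusted p = 0.0497; adjusted p = 0.424 with an estimated correlation) and interferon genes (adjusted p = 0.0258; adjusted p = 0.0926 with an estimated correlation) were shifted upward, with none passing; adjusted over the list alone 1 olfactory bulb marker rose. Shifted downward were oligodendrocyte genes (adjusted p = 0.000679; adjusted p = 0.152 with an estimated correlation) and endothelial markers (adjusted p = 0.0396; adjusted p = 0.152 with an estimated correlation), with none passing on either count. Glutamate receptors (adjusted p = 0.0373; adjusted p = 0.164 with an estimated correlation) and sodium, potassium and HCN channels (adjusted p = 0.0373; adjusted p = 0.0926 with an estimated correlation) were shifted downward with none passing. Calcium channel subunits were shifted downward as well (adjusted p = 0.0396, or adjusted p = 0.424 with an estimated correlation). Cacng2 fell and 18 of 19 did not pass on either count. That list holds the mutated gene itself, whose called probe sets changed by -5.26 and -3.61, against a list mean of -0.23. The shift therefore says little about the other subunits.

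The pituitary hormone transcripts Gh and Prl stood out on 3 forebrain arrays, with signals of 2603 and 2546 in stg+/+ replicate 1, 2102 and 2086 in stg+/+ replicate 2, and 3526 and 6052 in lh+/+ replicate 3. On cerebellum arrays Prl was also highest in stg+/+ replicates 1 and 2, at 108 and 247, and in lh+/+ replicate 3, at 297, against 1.46 to 56.8 on the other 15. Gh was 74.4, 230.5 and 90.1 on those 3 and up to 126 on the others. The labels do not say whether the tissues came from the same mice. The list of hypothalamus and pituitary genes had a mean of -0.91 and a median of 0.03 in stg forebrain and was not shifted (adjusted p = 0.927), and adjusted over the list alone 2 rose and 2 fell. Without those 3 arrays, an alternative chosen after seeing the data, the 1 stg+/+ array left was assumed to vary like the other groups, and 6 probe sets passed in stg forebrain, Arhgap39 not among them. The neuropeptide list then had an adjusted p of 0.0146 and a mean of 0.21. The other 7 lists did not pass, in a fit with less power, and the mean of each of the 8 lists had the same sign as before. It was -0.07 against -0.15 for oligodendrocyte genes, -0.06 against -0.11 for glutamate receptors and -0.14 against -0.23 for calcium channels. For the others it was 84.5% to 153% of its former size. The mean of the calcium channels includes the mutated gene Cacng2, so its kept sign says little about the other subunits. The lost lists ranged from 0.115, the adjusted p of the list olfactory bulb markers, stg forebrain, to 0.268, the adjusted p of the list voltage-gated calcium channel subunits, stg forebrain.

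The largest changes in tg cerebellum included Th, the rate-limiting enzyme of catecholamine synthesis, which rose from 30.6 ± 0.671 to 591 ± 35.6 (SD, n = 3), or 17.7-fold with the constant added to each signal (log2 4.15, SE 0.20, adjusted p = 6.96e-10). Tac1, the precursor of substance P, rose from 20.04 ± 4.62 to 117 ± 6.55 (2.40, SE 0.28, adjusted p = 0.000192). Gabra2, a GABA receptor subunit, fell from 252 ± 33.9 to 65.6 ± 16.3 (-1.92, SE 0.27, adjusted p = 0.00174), and another Gabra2 probe set was at -1.83. F2r, the thrombin receptor, fell from 462 ± 114 to 101 ± 14.95 (-2.13, SE 0.21, adjusted p = 4.32e-05). Pttg1 (5.11), the securin that holds back anaphase, Rec8 (4.88), a meiotic cohesin, Ssbp2 (3.55), Tmem267 (2.81), H2-K1 (2.55), a class I antigen-presenting molecule, Rcn2 (2.53), a calcium-binding protein of the endoplasmic reticulum, Sspn (2.46), Slc15a2 (2.38), a peptide transporter, the RNA-binding protein Msi2 (2.30) and Actr1a (2.12) also rose. Falls included Paip1 (-4.36), a translation factor, Mtrex (-4.04), an RNA helicase, Ccnb1ip1 (-3.15), H2-D1 (-2.64), the kinase Mapk14 (-2.31), Zkscan1 (-1.98), Ssu72 (-1.89), Thg1l (-1.87), Cuedc1 (-1.87) and the potassium channel Kcnj9 (-1.83). Rises and falls here compare tg-/- with tg+/+ only. For Pttg1 the log2 value was 8.82 in tg-/- and 3.71 in tg+/+, against 9.02 in stg+/+ and 6.76 in lh+/+. For Gabra2 (-1.92) it was 6.07 in tg-/- and 7.99 in tg+/+, against 6.42 in stg+/+ and 7.88 in lh+/+. Of 37 probe sets also called in tg forebrain, tg+/+ was farther than tg-/- from the mean of stg+/+ and lh+/+ in 19. In the other 18 tg-/- was farther.

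For probe sets changed, tg -/- versus +/+, cerebellum, the count was 155, 93 higher and 62 lower, in 107 named genes. Leaving out tg+/+ replicate 1, 2 or 3 gave 85, 63 or 74, and leaving out tg-/- replicate 2 or 3 gave 70 or 81. With array weights 390 passed. Probe sets of the class I genes can cross-hybridise and follow sequence variants, and those of H2-D1 moved apart: the called H2-D1 probe set fell by 2.64, while the others, at 4.35 (adjusted p = 0.139) and 4.83 (adjusted p = 0.129), did not pass. Names of class I genes are therefore uncertain here.

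Of the 12 lists shifted in tg cerebellum, 2 held with an estimated correlation. Interferon and antigen presentation genes were shifted upward, with 12 of 12 above 0 (mean 1.03, adjusted p = 6.06e-07, or adjusted p = 0.0336 with an estimated correlation). H2-K1 and H2-Aa (1.73) rose over all genes and 3 members rose adjusted over the list alone. The caution on class I genes applies to H2-K1, so the mean of this list rests in part on an uncertain reading. Microglia markers were shifted upward, 12 of 12 above 0, with the complement gene C1qc (1.12) rising over all genes and 2 adjusted over the list alone (mean 0.39, adjusted p = 1.22e-05; adjusted p = 0.0336 with an estimated correlation). Activity-regulated genes were shifted downward, with Ier2 (-0.78) falling, 23 of 24 not passing and 6 falling adjusted over the list alone (adjusted p = 0.000131; adjusted p = 0.175 with an estimated correlation). Sodium, potassium and HCN channels were shifted downward, with Kcnj9 falling on either count (adjusted p = 0.0228; adjusted p = 0.141 with an estimated correlation). Calcium buffering (adjusted p = 0.0315; adjusted p = 0.382 with an estimated correlation) and release genes (adjusted p = 0.0452; adjusted p = 0.382 with an estimated correlation) were shifted downward with none passing on either count. Granule cell markers were also shifted downward, with none passing over all genes and 1 falling adjusted over the list alone (adjusted p = 0.0464; adjusted p = 0.282 with an estimated correlation).

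Among cell type and region markers, those of astrocytes (adjusted p = 0.0227; adjusted p = 0.141 with an estimated correlation), oligodendrocytes (adjusted p = 0.0228; adjusted p = 0.418 with an estimated correlation) and choroid plexus (adjusted p = 0.0228; adjusted p = 0.558 with an estimated correlation) were shifted upward in tg cerebellum with none passing on either count. Striatum markers, with Tac1 rising and 2 rising adjusted over the list alone, were shifted upward (adjusted p = 0.0227; adjusted p = 0.141 with an estimated correlation). Glucocorticoid response genes were shifted upward with none passing over all genes and 1 rising adjusted over the list alone (adjusted p = 0.0227; adjusted p = 0.225 with an estimated correlation). The olfactory bulb list, which holds Th, had a mean of 0.57 and a median of -0.42 and was not shifted (adjusted p = 0.222). On the literature list Th rose and 14 of 15 did not pass; adjusted over the list alone 1 rose and 3 fell (list adjusted p = 0.877). In tg cerebellum Bdnf was at -0.92 (adjusted p = 0.170), Calb2 at -0.42 (adjusted p = 0.345) and the Gabra6 probe set of that list at -0.34 (adjusted p = 0.0888), and the other members were between -0.19 (Ryr1) and 0.26 (Cacna1c).

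The tg forebrain shared many of these changes but not those of Th and Tac1. Pttg1 rose from 70.5 ± 23.03 to 2413 ± 80.8 (SD, n = 3), a change of 5.10 (SE 0.94, adjusted p = 0.0252). Rps4l, a ribosomal protein gene copy, rose from 68.6 ± 14.8 to 269 ± 24.5, a change of 1.94 (SE 0.22, adjusted p = 0.000717). Gabra2 fell from 419 ± 32.9 to 133 ± 11.99 (-1.63, SE 0.29, adjusted p = 0.0201), and another Gabra2 probe set was at -1.27. Ptp4a2, a tyrosine phosphatase, fell from 1066 ± 216 to 412 ± 14.5 (-1.34, SE 0.18, adjusted p = 0.00178). Ssbp2 (4.28), Tmem267 (3.77), Rcn2 (2.82), Slc15a2 (2.67), Msi2 (2.14), Pou5f2 (1.92), Sh3pxd2b (1.82), Nxpe4 (1.69), Zfp593 (1.60) and the diacylglycerol kinase Dgke (1.58) also rose. Pdxdc1 (-5.43), Pigz (-2.57), Cuedc1 (-1.97), C130071C03Rik (-1.68), Wdfy1 (-1.59), the histone deacetylase Hdac9 (-1.04), Zdhhc18 (-1.03), the G protein subunit Gnb1, Sfxn4 (-0.91) and Itgb1bp1 (-0.61) fell.

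In tg forebrain 51 probe sets passed, 32 higher and 19 lower, in 34 named genes. Leaving out tg-/- replicate 1, 2 or 3 gave 24, 17 or 13, leaving out tg+/+ replicate 2 gave 29, array weights gave 117 and a fit without the intensity trend gave 27. Rps4l, Nxpe4, Ptp4a2 and Hdac9 passed under all alternatives and with each array left out, and the other named probe sets, Pttg1 and Gabra2 included, lost their call under at least 1. Of 24 lists, 3 were shifted, each lost with an estimated correlation. Activity-regulated genes were shifted downward, 25 of 27 below 0, with none passing over all genes and 9 falling adjusted over the list alone (mean -0.44, adjusted p = 3.12e-11; adjusted p = 0.222 with an estimated correlation). Endothelial markers were shifted downward with none passing on either count (adjusted p = 0.0239; adjusted p = 0.141 with an estimated correlation). Interferon genes were shifted upward with none passing over all genes and 3 rising adjusted over the list alone (adjusted p = 0.0190; adjusted p = 0.141 with an estimated correlation).

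Of the 50 tg forebrain calls measured in both tissues, 24 were also higher and 13 also lower in tg cerebellum. For independent lists 0.109 and 0.0428 would be shared. Mice shared by the 2 tissues, on which the labels are silent, would make the lists dependent. Pttg1, Ssbp2, Tmem267, Rcn2, Slc15a2, Msi2, Gabra2 and Cuedc1 were named in both tissues. The sign matched for 96.0% of the 50, and across probe sets, which are not independent replicates, the changes in the 2 tissues had a Pearson r of 0.402. The same value was 0.104 in stg, where 3 calls were shared, and 0.118 in lh, where 1 was.

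**Figure D2:**
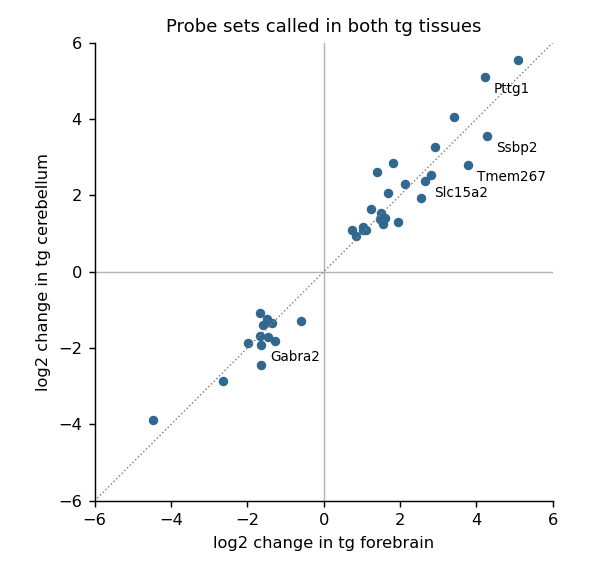
Log2 change of -/- against +/+ in tg forebrain and tg cerebellum for the 37 probe sets called in both tissues, 1 point each. The 24 higher and 13 lower probe sets lie on the same side of 0 in both tissues.

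In lh cerebellum Th rose from 47.8 ± 10.1 to 535 ± 52.1 (SD, n = 3), or 10.7-fold with the constant added to each signal (log2 3.42, SE 0.20, adjusted p = 2.10e-08). Tac1 rose from 37.6 ± 4.54 to 133 ± 44.7 (1.69, SE 0.28, adjusted p = 0.0115). Calb2, the calcium buffer calretinin, fell from 2707 ± 374 to 1469 ± 268 (-0.89, SE 0.14, adjusted p = 0.0112). Rbfox1, a neuronal splicing factor, fell from 1986 ± 16.6 to 1118 ± 59.6 (-0.83, SE 0.09, adjusted p = 0.000186). Hrk (1.67), an activator of apoptosis, Mrpl3 (1.58), a mitochondrial ribosomal protein, Rif1 (1.57), a replication timing factor, Tpd52l1 (1.21), Tmem100 (1.15), Fam117a (1.11), Cemip (1.06), which breaks down hyaluronan, Plxdc2, Antxr1 (0.74) and the noncoding RNA Neat1 (0.70) also rose. Falls included Fam199x (-2.08), Gsg1l (-1.35), an AMPA receptor partner, Stap2 (-1.11), the calcium-dependent kinases Camkk2 (-0.86), Camk1d (-0.73) and Camk4 (-0.62), Cacnb4, Clstn2 (-0.78), a synaptic adhesion protein, Ncald (-0.69) and Ank1 (-0.64).

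In lh cerebellum 42 probe sets passed, 15 higher and 27 lower, in 33 named genes. Leaving out lh-/- replicate 1 or lh-/- replicate 3 gave 16 in each case, leaving out lh+/+ replicate 2 or 3 gave 27 or 26, and the fit on the 6 arrays alone gave 6. Th, Cemip, Stap2 and Rbfox1 passed under all alternatives and with each array left out, and the other named probe sets, Tac1 and Calb2 included, lost their call under at least 1.

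**Figure D3:**
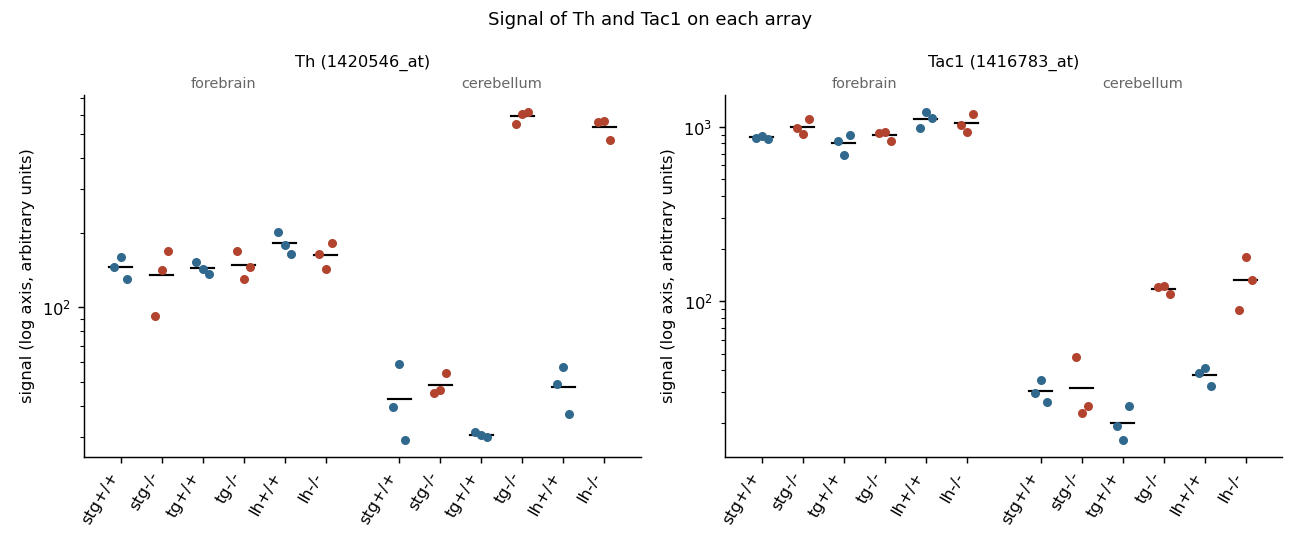
Signal of Th and Tac1 on each array, on a log axis, by line, genotype and tissue, with points for arrays and bars for the mean of 3. In cerebellum Th averages 591 in tg-/- and 535 in lh-/- mice against 30.6 and 47.8 in their +/+ groups, and 48.5 in stg-/- against 42.5 in stg+/+.

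Of 23 lists in lh cerebellum 14 were shifted, of which granule cell markers held with an estimated correlation. These markers were shifted downward, with 12 of 14 below 0, Calb2 falling over all genes and 6 adjusted over the list alone (median -0.19, adjusted p = 2.93e-07; adjusted p = 0.0207 with an estimated correlation). Calcium buffering genes were shifted downward, with Calb2 and Camk4 falling, 17 of 19 not passing and 3 falling adjusted over the list alone (adjusted p = 7.70e-06; adjusted p = 0.0744 with an estimated correlation). Purkinje markers were shifted downward with none passing on either count (adjusted p = 0.00949; adjusted p = 0.263 with an estimated correlation). Release genes were shifted downward with none passing over all genes, and 1 rose and 1 fell adjusted over the list alone (adjusted p = 0.0131; adjusted p = 0.166 with an estimated correlation).

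Markers of other cell types were shifted upward in lh cerebellum, with none passing over all genes. Adjusted over the list alone 7 of 17 oligodendrocyte genes rose (adjusted p = 7.06e-08; adjusted p = 0.0744 with an estimated correlation), as did 3 of 12 microglia markers (adjusted p = 2.32e-05; adjusted p = 0.0523 with an estimated correlation) and 3 of 14 astrocyte markers (adjusted p = 0.00387; adjusted p = 0.0744 with an estimated correlation). Ttr, the choroid plexus carrier of thyroxine, had a cerebellum signal of 6975 in lh+/+ replicate 3 and of 9299.8 to 13793 on the other 5 lh arrays, and Prl was 297 in lh+/+ replicate 3. Choroid plexus markers were above 0 in 15 of 15 with a mean of 1.09, and 1 rose adjusted over the list alone (adjusted p = 6.11e-08; adjusted p = 0.166 with an estimated correlation). Endothelial markers followed with none passing on either count (adjusted p = 0.0177; adjusted p = 0.107 with an estimated correlation), and 3 of 12 interferon genes rose adjusted over the list alone (adjusted p = 0.000992; adjusted p = 0.0760 with an estimated correlation). Glucocorticoid response genes were shifted upward, 1 rising adjusted over the list alone (adjusted p = 0.0301; adjusted p = 0.166 with an estimated correlation).

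Of lists that hold Th or Tac1, 2 were shifted upward in lh cerebellum. They were olfactory bulb markers (adjusted p = 0.00949, or adjusted p = 0.0760 with an estimated correlation) and striatum markers (adjusted p = 0.0301, or adjusted p = 0.148 with an estimated correlation). Of 5 olfactory bulb markers Th rose on either count and 4 did not pass on either. With Th at 3.42, that shift may rest largely on Th. Of striatum markers Tac1 rose, and 2 rose adjusted over the list alone. The literature list was shifted downward with 13 of 15 below 0, although Th rose; Calb2 fell, and adjusted over the list alone 1 rose and 3 fell (adjusted p = 0.00387; adjusted p = 0.0777 with an estimated correlation). Npy (-0.67), Gabra6 (-0.36), Ryr3 (-0.35), Gria4 (-0.25), Gabrd (-0.23), Pvalb (-0.22), Bdnf (-0.19), Gabrb2 (-0.18), Cacna1c (-0.15), Calb1 (-0.12), Ryr1 (-0.05), Gria2 (-0.03) and Ntrk2 (0.14) did not pass in lh cerebellum.

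In lh forebrain, besides Cacnb4, the dNTP hydrolase gene Samhd1 rose from 3.77 ± 0.867 to 61.1 ± 18.6 (SD, n = 3), a change of 3.21 (SE 0.51, adjusted p = 0.0336). The lh+/+ signal lies near the added constant of 2.98, so the size of this change too depends on the constant. Fam199x (-2.07, adjusted p = 0.0796), Pnma2 (1.64, adjusted p = 0.0796) and Iglon5 (2.06, adjusted p = 0.396) did not pass. In this comparison 4 of 27022 probe sets passed, 1 higher and 3 lower, and 1045 had an unadjusted p under 0.05. Without lh-/- replicate 1, lh+/+ replicate 1 or lh+/+ replicate 2 the count was 2, without lh+/+ replicate 3, which has high Gh and Prl, it was 1, and without lh-/- replicate 3, which had the lowest mean correlation with the other forebrain arrays, it was 8. The call of Samhd1 was lost when any 1 of the 6 arrays was left out, without the filter and without the intensity trend. None of 24 lists was shifted by camera, with 0.151 as the smallest adjusted p, and none passed with an estimated correlation or by fry.

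Lists never shifted in any comparison were GABA genes (adjusted p from 0.270 to 0.906), thalamus markers (0.589 to 0.972), hippocampus markers (0.276 to 0.782) and hypothalamus and pituitary genes (0.463 to 0.984). Brainstem and spinal cord markers, tested in forebrain, gave 0.690, 0.825 and 0.484. Mean and median had opposite signs in no shifted list. They did in 3 forebrain lists in stg (literature, granule cell, hypothalamus and pituitary), 5 in tg (calcium channels, Purkinje cell, choroid plexus, hypothalamus and pituitary, olfactory bulb) and 4 in lh (granule cell, Purkinje cell, hippocampus, hypothalamus and pituitary). In cerebellum they did in 8 lists in stg (calcium channels, calcium buffering, literature, endothelium, striatum, thalamus, hippocampus, olfactory bulb), 3 in tg (GABA, hypothalamus and pituitary, olfactory bulb) and 1 in lh (thalamus).

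**Figure D4:**
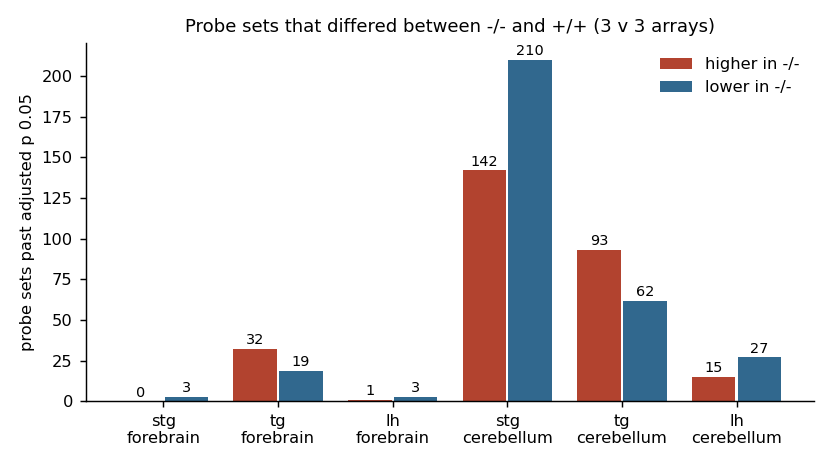
Number of probe sets higher and lower in -/- than in +/+ mice at adjusted p below 0.05, for each line and tissue, out of 27022. Cerebellum has 352, 155 and 42 calls in stg, tg and lh, and forebrain has 3, 51 and 4.

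Some genes were called in more than 1 line in cerebellum. A Gabra6 probe set other than that of the literature list fell in all 3 lines, at -0.65 in stg, -0.50 in tg and -0.42 in lh (SE 0.08 each). Stap2, a signalling adaptor, was also lower in each, at -0.74, -0.73 and -1.11 (SE 0.12 each). Th and Tac1 rose in tg and lh, as did Hrk (1.59 and 1.67), Tpd52l1 (1.01 and 1.21) and Fam117a. Camk4 (-0.76 and -0.62), Ncald (-1.57 and -0.69), the transcription factor Ets2 (-0.94 and -0.54) and the calcium sensor Vsnl1 (-0.85 and -0.55) fell in stg and lh. Nos1 rose in stg (1.60) and tg (0.65). In all, 10 probe sets were higher in 2 lines, 16 lower in 2 lines and 2 lower in 3.

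The lines have +/+ groups of their own, so the changes of different lines share no arrays. Their tests do share a common estimate of spread for each probe set, taken over all arrays of the tissue. A probe set with a low estimate is called more easily in every line, so the lists are not independent. The numbers for independent lists are therefore only a reference, and the excess over them may be overstated. In stg and tg 5 higher and 6 lower calls were shared, against 0.489 and 0.482 for independent lists. In stg and lh 14 lower calls were shared against 0.210, no higher call against 0.0788, and 1 call went opposite ways. In tg and lh 5 higher and 2 lower calls were shared, against 0.0516 and 0.0619. Of the 352 stg calls 73.9% had the same sign in tg and 76.1% in lh, and of the 155 tg calls 68.4% had the same sign in lh. Across all probe sets measured, which are not independent replicates, the cerebellum changes had a Pearson r of 0.106 for stg and tg, 0.0619 for stg and lh and 0.138 for tg and lh. In forebrain no call was shared between lines.

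**Figure D5:**
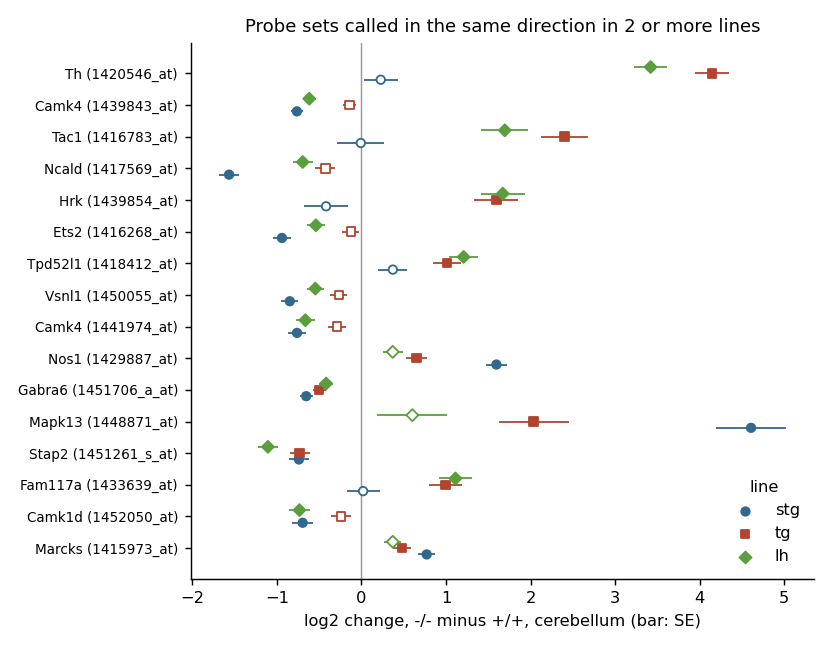
Log2 change of -/- against +/+ in cerebellum for the first 16 named probe sets called in at least 2 lines, with bars for SE and filled points for adjusted p below 0.05. Gabra6 and Stap2 are filled in all 3 lines, and Th and Tac1 in tg and lh.

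Averaged over the 3 lines, Th (2.60), Cacng2 (-2.19), Ncald (-0.90), Nos1 (0.87), Stap2 (-0.86), Rbfox1 (-0.55), Gabra6 (-0.52) and Camk4 (-0.51) had the smallest p in cerebellum, where 533 probe sets passed, 281 higher and 252 lower. For probe sets changed, mean effect of the 3 lines, cerebellum, without tg+/+ replicate 3 the count was 345, and without the intensity trend 341. A mean can rest on 1 line, as that of Cacng2 does. In forebrain 4 probe sets passed, 1 higher and 3 lower, with 1216 at an unadjusted p under 0.05 and Cacng2 (-1.83) as the only named gene. The forebrain count was 7 without tg+/+ replicate 2. It was 2 without stg-/- replicate 1 or 2, tg-/- replicate 1 or 3, lh-/- replicate 2 or lh+/+ replicate 3.

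The tissues differed in the effect of each mutation by a direct test. In stg the change of Ncald was lower in cerebellum than in forebrain by -1.57 (SE 0.16, adjusted p = 1.02e-06) and that of Nos1 higher by 1.44 (SE 0.17, adjusted p = 1.19e-05). In tg the change of Th differed by 4.11 (SE 0.27, adjusted p = 2.04e-11) and in lh by 3.57 (SE 0.27, adjusted p = 8.91e-10). Probe sets passing this test numbered 67 in stg, 7 in tg and 3 in lh. Array weights gave 133, 19 and 13. Without tg-/- forebrain replicate 3 or tg-/- cerebellum replicate 2 the tg count was 4, and without tg+/+ forebrain replicate 2 or tg-/- cerebellum replicate 3 it was 3. The lh count was 1 without lh+/+ forebrain replicate 2 or lh-/- cerebellum replicate 2, 7 without lh+/+ cerebellum replicate 1 and 5 without lh-/- forebrain replicate 3.

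Among the lines, the effect of the mutation differed for 85 probe sets in cerebellum. Cacng2, Th, the protease gene Adamts10, Cemip and F2r had the smallest p, and the changes of Th were 0.23, 4.15 and 3.42 in stg, tg and lh (adjusted p = 7.27e-07). The cerebellum count was 53 without stg+/+ replicate 1 or tg-/- replicate 3, 50 without tg-/- replicate 2, and 47 and 54 without tg+/+ replicates 2 and 3. In forebrain 7 probe sets passed, with Cacng2, Cacnb4, Rps4l, Nxpe4 and Tm2d2 as named genes. The forebrain count was 3 without tg-/- replicate 1, 2 or 3 or lh+/+ replicate 3, and 12 without lh-/- replicate 2.

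The +/+ groups of the 3 lines differed from each other at 112 probe sets in forebrain and 238 in cerebellum. These groups also differ in sex, with 2 females in stg+/+, 1 in lh+/+ and 3 males in tg+/+. In each tissue the first series of records holds 2 arrays of stg+/+ and of lh+/+ and 1 of tg+/+. The test does not separate line from sex or series. Clasp2, a microtubule plus-end protein, had forebrain signals of 1677, 807 and 1703 in stg+/+, tg+/+ and lh+/+ (adjusted p = 7.98e-06), and the cadherin gene Cdh7 had cerebellum signals of 115, 468 and 122 (adjusted p = 5.52e-07). Rcn2, which rose in tg, was 91.3, 13.0 and 6.55 in the +/+ cerebella (adjusted p = 9.47e-05), and Mrpl3, which rose in lh, was 43.6, 51.4 and 7.02 (adjusted p = 6.23e-05). Nkain2, Syt13, Ptp4a2, Pnma2, Nxpe4 and Wdr82 followed in forebrain, and Wdr82, 6430571L13Rik, Ptp4a2 and Stmn1 in cerebellum. Without lh+/+ replicate 2 or 3 the forebrain count was 61 or 54. The count of probe sets differing among the 3 +/+ groups, cerebellum, was 151 without lh+/+ replicate 2, and 135 and 139 without tg+/+ replicates 2 and 3.

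Genes within 10 Mb of the mutated gene were looked at in each comparison, since a segment of another strain's chromosome can travel with a mutation. In stg cerebellum Arhgap39, Cbx7, Foxred2, Ly6h, Rbfox2, Tef and 5031439G07Rik, 7 of the 178 measured genes in the Cacng2 window, were called (Fisher's exact p = 0.0918, adjusted p = 0.143). In tg cerebellum they were Ier2, Scoc and Zfp330, 3 of 112 (Fisher's exact p = 0.0761, adjusted p = 0.143), and in lh cerebellum Rif1, 1 of 38 (Fisher's exact p = 0.0955, adjusted p = 0.143). Arhgap39 was the called gene in stg forebrain, 1 of 177 (Fisher's exact p = 0.0141, adjusted p = 0.0849), and in tg and lh forebrain none of 113 and 39 was called (Fisher's exact p = 1 in each). The 12 calls summed over the 6 comparisons became 7 without tg-/- cerebellum replicate 2 or tg+/+ cerebellum replicate 2, 6 without the intensity trend and 26 over the whole chromosome.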

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

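Of the tests in this part, that of a smaller share of granule cells was chosen after the result was seen; the others were set beforehand.

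The results here are differences of the same mutation effect between tissues or between lines, each by a test of the difference itself. Between tissues, 67 probe sets differed in stg, 7 in tg and 3 in lh. In stg the change in cerebellum minus that in forebrain was -1.57 for Ncald, 1.54 for Kcnk2, 1.44 for Nos1, 2.22 for Homer2, 1.29 for Sox4, 1.79 for Scn3b, 1.80 for Inf2 and 1.62 for Igsf3. In tg it was 4.11 for Th, 2.25 for Tac1, -1.84 for F2r, -0.89 for Dipk1a, 0.93 for Nos1 and -0.73 for Stmn1, and in lh 3.57 for Th, 1.78 for Tac1 and 1.68 for Tmem100. Among lines, 7 probe sets differed in forebrain, where the range of the 3 changes was 5.30 for Cacng2, 1.33 for Cacnb4, 2.13 for Rps4l, 1.85 for Nxpe4 and 1.87 for Tm2d2. In cerebellum 85 differed, with ranges of 6.53 for Cacng2, 3.92 for Th, 1.46 for Adamts10, 1.77 for Cemip, 2.52 for F2r, 2.07 for Aqp6, 1.48 for Sfpq and 1.098 for Doc2b.

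Other splits of the arrays were counted, 100 drawn with the real split included. For the tissue difference in stg 11 of 100 gave at least the real 67, the highest other 132; in tg 6 of 100 gave at least 7, the highest 360; and in lh 5 of 100 gave at least 3, the highest 11. For the line difference in forebrain 6 of 100 gave at least 7, the highest 32. For these 4 results chance is not excluded by this count, but the count could hardly exclude it. A draw can keep the real -/- and +/+ split of a line in a tissue, and a real effect there then recurs. Of 99 draws, 22 for stg, 13 for tg, 16 for lh and 20 for the forebrain lines held such a split. Among draws at least as large as the real count, all 10 for stg, 5 of 5 for tg and 5 of 5 for the forebrain lines held one. The highest draws without one gave 39, 6 and 2. For lh 2 of 4 held one, and the highest without gave 11. For the line difference in cerebellum 4 of 100 gave at least 85, the highest 314, so chance is excluded at a share of 0.05, and the highest draw without a real split gave 2.

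The higher Th signal in tg-/- and lh-/- cerebellum was weighed first. Forebrain tissue carried along would raise forebrain transcripts with it, but the 50 probe sets most typical of forebrain had medians of 0.039 (SD 0.71) in tg and 0.045 (SD 0.59) in lh, far under the Th changes of 4.15 and 3.42. Catecholamine neurons of the brainstem would bring their other markers, and the higher of the 2 medians of 7 such markers was 0.12, with Dbh at -0.20 and 0.12, Ddc at 0.08 and 0.06 and the noradrenaline transporter Slc6a2 at -0.32 and 0.66 (SE 0.40) in tg and lh. In tg the highest of the 7 was at 0.56, within the limits set beforehand, but in lh the dopamine transporter Slc6a3 was at 2.14 (SE 0.65), over its limit though from a signal of 2.78 at the floor to 24.1, and 4 of the 7 markers, Slc6a3 included, lay below the filter, so this stays open. A candidate explanation is induction of Th within cerebellar neurons by the mutations, which these arrays do not test directly.

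The changes in stg-/- cerebellum were weighed next. A smaller share of granule cells would lower their markers. The granule list had a median of -0.082 (SD 0.24) against -0.78 for the 210 that fell, so the list as a whole did not fall by that much. Those 210 were picked from the same data as falls that passed, so their median is large by construction. The comparison therefore cannot exclude a smaller loss of granule cells. Forebrain tissue carried along would raise the 50 probe sets most typical of forebrain, which had a median of 0.092 (SD 0.61) against 0.76 for the 142 that rose. Those 142 were likewise picked from the same data as rises that passed. Their median too is large by construction, so this comparison cannot exclude a small amount of forebrain tissue. Of the risen probe sets with a value in both tissues, 54.6% are higher in normal forebrain against 21.0% of all tested. This is a ratio of 2.60, which met the limit set beforehand, while the ratio was 0.657 for the fallen. A rise within the cerebellum of some transcripts that are higher in forebrain may be part of the pattern, as a hypothesis. It would not extend to the most forebrain-typical ones as a set, of which 28 of 50 were above 0. The share was 53.3% of 15 risen probe sets in lh (21.4% of all tested) and 26.7% of 90 in tg (21.0%). Differences between lines were not tested.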

How the results depend on the processing

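No result that was called in the main fit or under an alternative had opposite directions in the 2. Changes of sign of results called in neither were not counted. Quantile normalization, a constant of 1, the stricter filter and windows of 5 and 20 Mb left every count within 1.5 times its value. Without the filter the mean effect in forebrain fell to 2. Without the intensity trend the counts were 27 in tg forebrain, 2 in lh forebrain, 341 for the mean effect in cerebellum, 3 and 47 for differences among lines in forebrain and cerebellum, 60 and 135 among the +/+ groups, and 6 near a mutated gene. Array weights gave 5, 117 and 9 in stg, tg and lh forebrain, 390 for probe sets changed, tg -/- versus +/+, cerebellum, 15 for the mean effect in forebrain, 133, 19 and 13 for tissue differences in stg, tg and lh, 17 and 180 for differences among lines, and 187 and 518 for probe sets differing among the 3 +/+ groups, forebrain and probe sets differing among the 3 +/+ groups, cerebellum. The fit on the 6 arrays compared gave 194 in stg and 6 in lh cerebellum, with fewer arrays to estimate the spread. Camera with an estimated correlation left 4 of the 41 shifted lists. Fry passed 17 lists, 16 of them among the 41 and the other the olfactory bulb list in tg cerebellum. The whole chromosome gave 26 calls, since it holds more genes. Chosen after seeing the data, a block for the 2 series of records gave 77 and 2 in tg and lh forebrain, 689, 287 and 137 in stg, tg and lh cerebellum, and 7 and 988 for the mean effect in forebrain and cerebellum. Leaving out the 3 arrays with pituitary transcripts, also chosen then, gave 6 in stg forebrain. Except where construction shows it, the cause was not tested.

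Leaving out 1 array at a time gave ranges of 1 to 8 in lh forebrain, 13 to 36 in tg forebrain, 225 to 291 in stg, 63 to 116 in tg and 16 to 36 in lh cerebellum. The ranges were 2 to 7 for the mean effect in forebrain, 345 to 500 for probe sets changed, mean effect of the 3 lines, cerebellum, 3 to 8 and 1 to 7 for tissue differences in tg and lh, 3 to 12 and 47 to 92 for differences among lines, 54 to 107 among the +/+ groups in forebrain, 135 to 217 for probe sets differing among the 3 +/+ groups, cerebellum, and 7 to 12 near a mutated gene. A fit with 2 arrays in a group has less power by construction. Named called probe sets that passed everywhere numbered 27 of 47 in stg, 15 of 32 in tg and 4 of 27 in lh cerebellum, and 2 of 3, 4 of 25 and 1 of 4 in stg, tg and lh forebrain.

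With the replicate number as a block the counts were 1018, 429 and 211 in stg, tg and lh cerebellum, 1237 for the mean effect and 480 for differences among lines in cerebellum, and all 352, 155 and 42 calls of the lines stayed called. Of the named probe sets it added calls of Calb1, Pvalb and Gabrd in stg, Gabra6 and Ncald in tg, and Gabra6 and the other Cacnb4 probe sets in lh. Of the list calls in cerebellum that of striatum markers in lh was lost. Over the 3 lines the numbers were not taken to pair the arrays: of 9 same-numbered pairs in cerebellum 7 had correlated deviations over 0.1, from 0.0404 to 0.380, although 8 of 9 correlated best with their own number, a hint from the data and not from the design. The 3 stg pairs were each over 0.1, at 0.156, 0.188 and 0.380. The block was not run for comparisons across +/+ groups, since it holds the line. Signals near the floor limit small changes most, because the constant shrinks them.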

Other observations

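Of the tests in this part, those of the tg mutation and of genetic background, and the block for the series of records, were chosen after the result was seen; the test without tg+/+ forebrain replicate 2 and the counts of other splits were set beforehand.

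Ttr, the choroid plexus carrier of thyroxine, had a cerebellum signal of 3624 in stg+/+ replicate 2 and of 9811 to 14211 on the other 5 stg arrays.

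The 37 probe sets called in the same direction in tg forebrain and tg cerebellum were weighed as a pattern. If the mutation moved all of them, tg-/- would mostly stand apart from the +/+ mice of the other lines. The tg+/+ genotype was farther from the mean of stg+/+ and lh+/+ in 51.4% of the 37 in cerebellum (Clopper-Pearson interval 34.4% to 68.1%). In forebrain it was farther in 45.9% (29.5% to 63.1%). The intervals treat probe sets as independent, although some share a gene, such as Gabra2. The count cannot decide, because stg+/+ and lh+/+ differ from each other at some of the 37. Cerebellum log2 values of Rcn2 were 6.53 in stg+/+ and 3.20 in lh+/+, against 6.51 in tg-/- and 3.98 in tg+/+. The count leaves open which of the 37 the mutation moved. The array tg+/+ forebrain replicate 2 does not carry the pattern, since without it 51.4% were still called in forebrain, within the 27.0% to 56.8% for leaving out any other tg array, and 37 of 37 kept their direction. Genetic background that differs between tg-/- and tg+/+ mice is a candidate explanation. Of 146 tg cerebellum calls, 24 also differed among the +/+ groups in forebrain, 39.7 times the 0.605 of independent lists. In stg it was 1 of 323 against 1.34, and in lh 0 of 40 against 0.166. Some of the tg calls may thus mark strain variants rather than a response to the mutation. The lh count does not exclude this for single lh calls. Mrpl3, which rose in lh cerebellum, was lowest in lh+/+ among the +/+ cerebella.

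Splits of 3 arrays against 3 number 10, too few for a share under 0.05. The real count and the highest of the other splits were 3 and 5 in stg forebrain, where 2 of 10 gave at least 3. They were 51 and 0 in tg forebrain, 4 and 1 in lh forebrain, 352 and 6 in stg cerebellum, 155 and 0 in tg cerebellum and 42 and 2 in lh cerebellum, each with 1 of 10 as large. Of 100 joint draws, 5 gave at least the 4 probe sets of the mean effect in forebrain, which does not exclude chance. This count too could hardly exclude it, since 20 of 99 draws held the real split of a line in forebrain. Of the 4 other draws that large 3 did. The highest, 292, did not. It placed 6 more arrays of the first series of records on 1 side than on the other, and a block for these series gave 7. For the mean effect in cerebellum 1 of 100, the real split, reached 533, the highest other 144, so chance is excluded. The same holds, with 1 of 100, for the 112 and 238 probe sets that differ among the +/+ groups (highest others 47 and 73). It also holds for the 15726 between tissues (12543) and for the number of shifted lists, 41 (29). Every other draw shifted lists too, from 3 up to 29, and up to 17 in draws without the real split of a line. The list test thus calls some lists under random splits, and single lists among the 41 may be due to chance. For the 12 calls near a mutated gene 1 of 100 was as large and the highest other gave 10, but this count follows the number of calls anywhere and says nothing about position, for which no Fisher's exact test passed after adjustment.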
